A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

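Messenger RNA levels of commercial baker's yeast, Saccharomyces cerevisiae, were measured after frozen storage of 0, 3, 7 or 14 days. Per the labels' protocols, compressed yeast was suspended at an OD600 of 30 in a liquid fermentation medium lacking sucrose and maltose, held at -20 °C and thawed for 10 min at 30 °C. RNA was taken by hot phenol extraction and enriched for poly(A) RNA on oligo(dT) particles, and biotin-labelled cRNA was prepared by the array maker's manual, per the labels' protocols. Each of the 4 times had 2 samples, which the submitters describe as independent duplicates, and each sample was read on 1 Affymetrix array, giving 8 arrays.

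The deposited values are probe set intensities on a linear scale, 1 column per array, all above 0. The software that summarised probes into probe sets, and any scaling, are not given in the sources used here. The 2% trimmed means of the deposited intensities ran from 182 to 415, a ratio of 2.28, so the columns did not share a common scale. Depth has no counterpart on arrays, and their number limits the precision. Detection calls were not used here.

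The table held 9335 probe sets, of which 60 were controls. A platform annotation assigned 6504 of the others to exactly 1 gene and 328 to several, and 2443 carried no gene name. These matched 5656 genes, and no gene was named from a probe set with several genes. Gene identifiers were set against the RefSeq table of assembly R64, which changed 0 symbols, and no coordinates were used.

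Control probe sets were removed. The arrays were quantile normalised, values below the pooled 5th percentile (2.52 on the linear scale) were raised to it, and log2 was taken. The rule fixed in advance was to normalise unless the array means lay within 5% of one another. Probe sets whose mean over the 8 arrays lay below the 25th percentile (4.16 on the log2 scale) were left out. Each gene was represented by its brightest probe set, which left 5188 genes. Of these, 244 had more than 1 probe set past the filter. Where probe sets of a gene named by the rule below differed, both values are in the text. For most other genes named in the text, further probe sets were not compared.

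Differences were tested in R 4.3.3 with limma 3.58.1. A linear model with 1 coefficient per freezing time was fitted to all 8 arrays (4 residual degrees of freedom), followed by empirical Bayes moderation with an intensity trend (6.89 prior degrees of freedom). All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the genes tested within each comparison, and every adjusted p of a gene below is of this kind. Genes with an adjusted p under 0.05 were called. The comparisons were 3, 7 and 14 days against 0 days, the mean of the 3 frozen groups against 0 days, the pairs of frozen groups, and a moderated F test among the frozen groups.

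Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Every test was repeated with the correlation estimated for each list, and with fry, which asks whether the members of a list move on balance one way. There were 38 lists on stress responses, protein production and turnover, carbon and energy metabolism, membranes, the cell wall, nutrient uptake and cell state. Of these, 37 had at least 5 measured members and were tested. The lists, the designs, the rule for naming genes and most alternatives were fixed before the data were examined.

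By that rule, the text names the 5 genes with the largest rise and the 5 with the largest fall among called genes whose arrays did not overlap between the groups compared. Where none was called, the 3 most extreme each way are given as values. It also names up to 2 called members of each of the 6 lists with the smallest camera p (4 lists for 14 against 3 days), or the 2 with the smallest p where none was called, the 2 largest each way for 7 against 3 days, and 13 genes fixed by name: HSP104, HSP12, HSP26, SSA4, UBI4, CTT1, SOD2, TPS1, TSL1, GPD1, ERG11, OLE1 and RPN4. Other genes named in the text were chosen after their values were seen. These include IDH1, HAP4 and TIP1, the called members of lists with few calls, and the genes called for the mean of the frozen groups.

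Control probe sets were read on the deposited scale. The ratio of 3' to 5' signal of ACT1 and SPT15, the spiked poly(A) transcripts, the hybridisation controls and the ribosomal RNA probe sets were taken per array. Within each freezing time, the array with the lower mean log2 signal of the spiked poly(A) transcripts was put into set 1 and the other into set 2, so each set holds every time by construction. Set 1 held 0 day replicate 1 and replicate 2 of 3, 7 and 14 days, and set 2 held the other arrays. Values within each set are given beside the lists, and the set was added as a block in an alternative chosen after the data were seen. Against 0 days the sets cross the replicate numbers of the labels. Values within a set against 0 days therefore show only 1 way to pair the arrays, and pairing by replicate number would give others. The block changes standard errors and leaves fold changes as they are.

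Correlations of fold changes between comparisons that share the 0 day arrays were set against 100 simulations of unchanged groups with each gene's residual spread. That spread was the same at every time, so a larger spread at 0 days would make the simulated covariance too low. The tests were checked on 20 simulated data sets of 5169 genes built on the 14 against 0 day comparison, with 200 genes changed. They recovered 83.6% of 8-fold changes and 6.60% of 2-fold changes, with 6.16% of calls false. A shifted list was called in 20 of the 20 sets. The simulated genes varied independently, so this cannot decide whether the preset correlation suits the measured lists. Their estimated correlations ran from -0.0321 for the vacuolar proton ATPase to 0.603 for gluconeogenesis, with 0.222 for heat shock proteins. The vacuolar proton ATPase list lay below the preset 0.01. It still lost its call between 3 and 14 days in the repeat (camera adjusted p = 0.339), so the correlation alone does not account for lost calls.

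The alternatives were the deposited intensities without normalisation, equal array medians, no floor, a pseudocount at the pooled 25th percentile, no filter on dim probe sets or a filter at the median, no intensity trend, array quality weights, a fit to the compared groups alone, the replicate number as a block, stricter thresholds, all probe sets counted, a rule of at least 2-fold in all pairings of arrays, and each of the 8 arrays left out in turn. Where an array was left out, the remaining array of its time was assumed to vary like the other groups. The list of transcripts encoded in mitochondrial DNA had too few measured members and was left out.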

Results

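The series asked how the messenger RNA of baker's yeast differed after thawing when the cells had been frozen for different lengths of time. Samples kept at -20 °C for 3, 7 and 14 days were compared with samples of 0 days, with n = 2 independent samples per time. Median deposited signals ran from 51.7 to 110 across the 8 arrays. The median standard error of a log2 fold change was 0.45, and with 2 arrays per time the number of arrays limited the precision.

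The arrays fell mainly into early and late freezing times. The first principal component held 39.6% of the variance and separated all 0 and 3 day arrays from all 7 and 14 day arrays. Replicates correlated across genes at r = 0.912 for 3 days, 0.938 for 7 days and 0.927 for 14 days. At 0 days the replicates correlated at r = 0.877, and 0 day replicate 2 was closer to 3 day replicate 1 (r = 0.935). Genes are not independent replicates, so these correlations describe the arrays only. Ribosomal RNA probe sets stood on average 8.85 and 6.76 times above the array median at 0 days and 7.75 and 11.3 times at 3 days. They stood 17.1 and 22.7 times above it at 7 days and 21.7 and 15.7 times at 14 days.

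After 14 days of freezing, the lists of heat shock proteins and mitochondrial ribosomal proteins lay above their 0 day levels and those of ribosomal proteins and amino acid biosynthesis below. Camera called these lists with the preset correlation, each with adjusted p = 0.324 with an estimated correlation. Of the 5188 genes tested, 52 rose and 38 fell (limma, Benjamini-Hochberg adjusted p under 0.05), all of them by at least 2-fold. ROQ1, whose product redirects the ubiquitin ligase Ubr1 to misfolded proteins, rose 16.5-fold (log2 fold change 4.05 ± 0.50 SE, n = 2 per group, limma adjusted p = 0.0140). RNR1, the large subunit of ribonucleotide reductase, fell 14.5-fold (log2 fold change -3.86 ± 0.47 SE, limma adjusted p = 0.0140).

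The other large rises after 14 days were ECM13 (log2 fold change 3.89), YHR022C (3.79), the phospholipid synthesis activator INO2 (3.43) and ROX1, the repressor of hypoxic genes (3.35). YHR022C had a mean signal of 3.39 at 0 days, close to the floor of 2.52, so its fold change is less certain. The other large falls were ADY4, a spindle pole component of meiosis (-4.07), RNR3, a second large subunit of ribonucleotide reductase read by a probe set that can bind related transcripts (-3.82), the acid phosphatase PHO3 (-3.19) and the oligopeptide transporter OPT2 (-2.97). ADY4 was close to the floor in 14 day replicate 1 (signal 2.79), and its value was -2.90 without that array. The calls of ADY4 and YHR022C each ended in 9 of 18 alternatives and that of INO2 in 9 of 19. Limma adjusted p for these ranged from 0.0140 for ROX1 to 0.0415 for INO2. Both 14 day arrays lay beyond both 0 day arrays for each gene, which the naming rule required and which adds no support. POL30, the sliding clamp of DNA replication, fell too (-2.81, limma adjusted p = 0.0287), and with RNR1 and RNR3 it made up the 3 called members of the DNA damage list. That list as a whole was not called by camera (adjusted p = 0.147).

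Of 32 measured genes for heat shock proteins and co-chaperones, 7 rose after 14 days and 0 fell over all genes tested, and 24 rose when adjusted over the list alone. The median log2 fold change was 1.21, and 1.03 within array set 1 and 1.23 within set 2. The called genes included the Hsp110 chaperone SSE2 (log2 fold change 2.05 ± 0.45 SE, limma adjusted p = 0.0485) and HSP82, a form of Hsp90 (1.86 ± 0.37 SE, limma adjusted p = 0.0381). The probe set of HSP82 can also bind the near-identical HSC82, so its values may combine both genes. The call of SSE2 ended in 11 of 19 alternatives and that of HSP82 in 8. The camera adjusted p was 2.56e-12 with the preset correlation and adjusted p = 0.324 with an estimated correlation.

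Among 51 general stress genes of the Msn2 and Msn4 type, HSP12 alone rose over all genes tested (log2 fold change 1.28 ± 0.26 SE, limma adjusted p = 0.0381), and 13 rose when adjusted over the list alone. HSP12 encodes a small membrane-protecting heat shock protein, and its call ended in 9 of 19 alternatives. The median of the list was 1.28, but 0.40 within set 1 and 2.23 within set 2, and it was 0.61 without 0 day replicate 2. With the preset correlation, camera gave adjusted p = 1.95e-08 for this list, against adjusted p = 0.395 with an estimated correlation. The remaining fixed genes were not called at 14 days. The catalase CTT1 had a log2 fold change of 3.30 ± 0.87 SE (limma adjusted p = 0.0773) with 0 day replicate 1 at the floor, and passed the threshold on unnormalised values and without 0 day replicate 2. Values were 1.80 for the chaperone SSA4, 1.84 for HSP26, 1.54 for the superoxide dismutase SOD2, 1.21 for the proteasome gene activator RPN4 and 1.02 for the disaggregase HSP104, and all 5 passed the threshold on unnormalised values. SSA4 also passed it with a filter at the median and with array set as a block, and HSP26, TPS1 and GPD1 without 0 day replicate 1. Values were 1.09 for the trehalose synthase TPS1, 0.62 for its regulatory subunit TSL1, 0.88 for the glycerol synthesis enzyme GPD1, 0.44 for the polyubiquitin gene UBI4, 0.41 for the fatty acid desaturase OLE1 and -0.21 for the ergosterol enzyme ERG11. GPD1, OLE1 and TSL1 were below 0 without 0 day replicate 2, at -0.27, -0.27 and -0.77, and TPS1 was at 0.07, against 2.15 without 0 day replicate 1. ERG11 was above 0 on unnormalised values (0.01) and without 14 day replicate 1 (0.34).

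Of 81 measured genes for cytosolic ribosomal proteins, 4 fell after 14 days over all genes tested and 36 fell when adjusted over the list alone, where 1 rose. The 4 were RPS1B (log2 fold change -2.32 ± 0.31 SE, limma adjusted p = 0.0140), RPL33A (-1.47 ± 0.31 SE, limma adjusted p = 0.0417), RPL25 (-1.20) and RPS22A (-1.09). RPS1B and RPL33A were read by probe sets that can also bind a near-identical copy, so these values may combine both genes. The call of RPL33A ended in 12 of 19 alternatives. The median of the list was -0.60, with -0.57 within set 1 and -0.62 within set 2. For this list, the camera test gave adjusted p = 1.48e-18 with the preset correlation and adjusted p = 0.324 with an estimated correlation.

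Among 54 amino acid biosynthesis genes of the Gcn4 type, 5 fell after 14 days and 0 rose over all genes tested, and 17 fell and 1 rose when adjusted over the list alone. All 5 belong to lysine synthesis: LYS9 (log2 fold change -2.91 ± 0.42 SE, limma adjusted p = 0.0155), LYS12 (-2.45 ± 0.40 SE, limma adjusted p = 0.0226), LYS2 (-1.93), LYS1 (-1.77) and LYS4 (-1.76). The list median was -0.62, with -0.78 within set 1 and -0.54 within set 2, and ran from -0.73 to -0.12 over the alternatives. Camera gave adjusted p = 8.02e-08 with the preset correlation and adjusted p = 0.324 with an estimated correlation. The 22 aminoacyl-tRNA synthetases had a median of -0.71 (-0.64 within set 1 and -0.96 within set 2), which ran from -0.86 to -0.24 over the alternatives. Of these genes, 0 were called over all genes tested by limma and 2 fell when adjusted over the list alone. Their members with the smallest p were CDC60 (-1.46, limma adjusted p = 0.0671) and YHR020W (-1.29, limma adjusted p = 0.0834). The list was called by camera (adjusted p = 4.21e-07 with the preset correlation) but not when repeated, with adjusted p = 0.324 with an estimated correlation.

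In the TCA cycle after 14 days, 3 of 19 genes rose over all genes tested and 6 rose when adjusted over the list alone. These were IDH1 (log2 fold change 2.56 ± 0.40 SE, limma adjusted p = 0.0173), the aconitase ACO1 (2.22) and the fumarase FUM1 (1.90). The median of the list was 1.07, but 0.17 within set 1 and 1.91 within set 2, and 0.54 without 0 day replicate 2, where the call of camera ended. Relative to the 0 day mean, replicates 1 and 2 lay at 0.48 and -0.48 at 0 days. They lay at 1.32 and 0.93 at 14 days, so pairs by replicate number lie closer together than the sets. Camera gave adjusted p = 5.86e-05 with the preset correlation and adjusted p = 0.350 with an estimated correlation. Among 44 nuclear genes of the respiratory chain, 2 rose over all genes tested and 3 when adjusted over the list alone, with a median of 0.60 (0.18 within set 1 and 1.20 within set 2). These were HAP4, the activator of respiratory genes (log2 fold change 2.55 ± 0.37 SE, limma adjusted p = 0.0155), and the copper chaperone SCO1 (1.69). The call of camera ended without 0 day replicate 2 (median 0.38) and without 14 day replicate 1 (0.41). With the preset correlation, camera gave adjusted p = 1.00e-04 for this list, against adjusted p = 0.437 with an estimated correlation. The 67 mitochondrial ribosomal protein genes had a median of 0.70 (0.75 within set 1 and 0.49 within set 2), and 0.44 without 0 day replicate 1. Of these, 0 were called over all genes tested by limma and 5 rose when adjusted over the list alone, with MRPL40 at 1.74 (limma adjusted p = 0.0576) and MRPL28 at 1.73 (limma adjusted p = 0.0561). For this list, the camera test gave adjusted p = 7.95e-06 with the preset correlation and adjusted p = 0.324 with an estimated correlation.

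Of 24 iron and copper uptake genes, 3 fell after 14 days over all genes tested and 8 fell when adjusted over the list alone. The vacuolar iron transporter SMF3 fell 7.36-fold (log2 fold change -2.88 ± 0.38 SE, limma adjusted p = 0.0140), and the iron permease FTR1 (-2.33) and the low-affinity transporter FET4 (-2.07) fell as well. The list median was -0.56, with -0.90 within set 1 and -0.46 within set 2, and with -0.31 and -0.86 without 0 day replicates 1 and 2. It was 0.01 on unnormalised values, where the median of all genes was 0.59. The list was called by camera (adjusted p = 1.25e-04 with the preset correlation) but not when repeated, with adjusted p = 0.350 with an estimated correlation. In the oxidative stress list, the peroxiredoxin TSA1 rose (1.94, limma adjusted p = 0.0397), 5 of 42 genes rose when adjusted over the list alone, and the median was 0.68 (0.37 within set 1 and 1.17 within set 2). Without 0 day replicate 2 it was 0.43 and the call of camera ended, and without 0 day replicate 1 it was 1.10. Camera gave adjusted p = 5.86e-05 with the preset correlation and adjusted p = 0.350 with an estimated correlation.

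**Figure D1:**
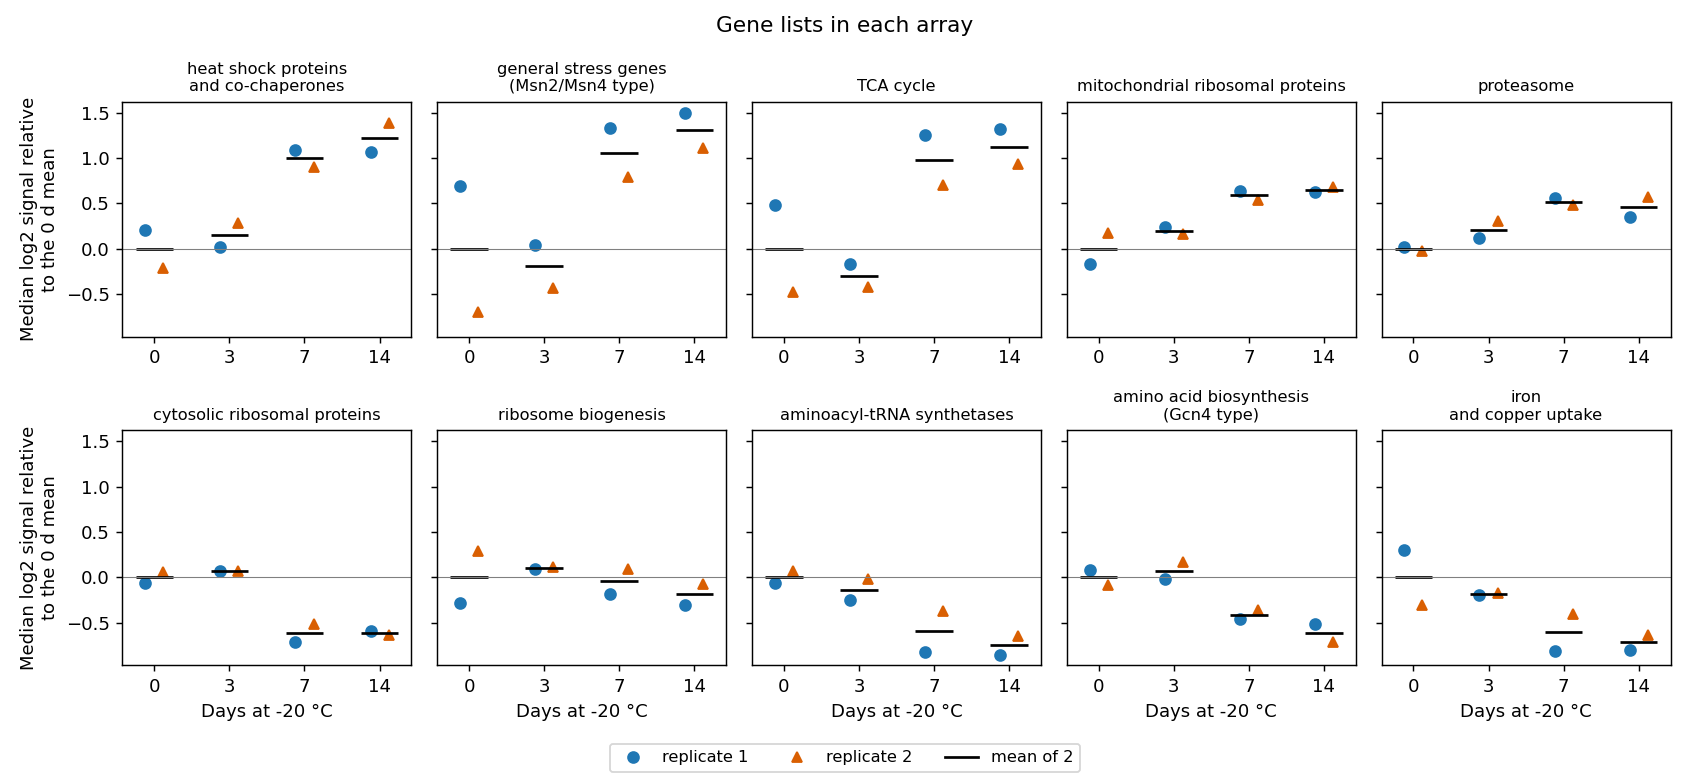
Median log2 signal of 10 gene lists in each of the 8 arrays, relative to the mean of the 0 day arrays, against days at -20 °C. Circles are replicate 1, triangles replicate 2 and lines the mean of both. The heat shock list lay at 1.06 and 1.38 in the 14 day arrays, and the ribosomal protein list at -0.59 and -0.63.

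In all, camera called 22 of 37 lists at 14 days with the preset correlation, 12 higher and 10 lower. With an estimated correlation camera called 0, with a smallest adjusted p of 0.324, and fry called 9. That form of camera also has only the 4 residual degrees of freedom, so the loss cannot be laid to the correlation alone. Without 0 day replicate 2, camera called 12 lists, 3 of them higher, and without 14 day replicate 1 it called 14, of which 6 were higher. Unadjusted p was under 0.05 for 1151 genes, where 259 were expected by chance. The late samples that carry these shifts also had the higher ribosomal RNA signals, by 1.26 on the log2 scale at 14 days against 0 days. The count of 90 genes became 0 without either 14 day array and 245 without 0 day replicate 1, and was 52 without 0 day replicate 2, 39 and 41 without 3 day replicates 1 and 2, and 52 without 7 day replicate 2. It was 0 with only the compared groups in the fit, 11 without the intensity trend and 17 with array weights. With array set as a block it was 222. On unnormalised values 386 of 403 called genes were higher, and with equal array medians 35 of 48, against 52 of 90 here, where the median of all genes was 0.11.

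After 7 days, 11 genes differed from 0 days. In limma, 6 genes rose and 5 fell (Benjamini-Hochberg adjusted p under 0.05). ROQ1 rose 13.1-fold (log2 fold change 3.71 ± 0.50 SE, n = 2 per group, limma adjusted p = 0.0229), and the mitochondrial dicarboxylate carrier DIC1 rose 8.24-fold (3.04 ± 0.44 SE, limma adjusted p = 0.0229). RNR1 fell 9.84-fold (-3.30 ± 0.47 SE, limma adjusted p = 0.0229) and OPT2 8.11-fold (-3.02 ± 0.42 SE, limma adjusted p = 0.0229).

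The other rises at 7 days were the proteasome-binding protein FUB1 (log2 fold change 3.65), YNR014W (3.04), MIC10, a subunit that shapes mitochondrial cristae (1.72), and the cold-induced mannoprotein TIP1 (1.66, limma adjusted p = 0.0499). A second probe set of MIC10 gave 1.20. The other falls were LYS9 (-2.82), SMF3 (-2.66) and RPS1B (-2.08). The call of MIC10 ended in 11 of 19 alternatives, those of YNR014W and RPS1B in 10 and that of SMF3 in 8. All 6 genes that rose and all 5 that fell at 7 days were also called in the same direction at 14 days, where 0.0601 and 0.0366 shared genes would arise from independent lists. The comparisons share the 0 day arrays, so part of this overlap may come from them. Across genes, fold changes at 7 and 14 days correlated at r = 0.873, where simulated unchanged groups gave 0.50. The covariance exceeded the simulated one by 0.499, which may be too large, since the simulation gave the 0 day arrays no more spread than the others. With a different 0 day array for each comparison, r was 0.357 or 0.385.

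Heat shock genes had a median log2 fold change of 1.08 at 7 days, with 0.65 within set 1 and 1.33 within set 2. Of these, 0 of 32 were called over all genes tested by limma and 22 rose when adjusted over the list alone. FES1, an exchange factor of Hsp70, had a value of 1.28 (limma adjusted p = 0.0505) and HSP82 one of 1.92 (limma adjusted p = 0.0566). With the preset correlation, camera gave adjusted p = 4.36e-11 for this list, against adjusted p = 0.357 with an estimated correlation. Ribosomal protein genes had a median of -0.61, with -0.43 within set 1 and -0.79 within set 2. RPS1B fell over all genes tested, and 36 fell and 1 rose when adjusted over the list alone. For this list, the camera test gave adjusted p = 8.64e-22 with the preset correlation and adjusted p = 0.349 with an estimated correlation.

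General stress genes had a median of 0.95 at 7 days, but 0.08 within set 1 and 1.88 within set 2, and 0.31 without 0 day replicate 2, where the call of camera ended. Of 51 genes, 0 were called over all genes tested by limma and 4 rose when adjusted over the list alone. The list was called by camera (adjusted p = 4.15e-06 with the preset correlation) but not when repeated, with adjusted p = 0.556 with an estimated correlation. HSP12 was at 1.24 (limma adjusted p = 0.0608), the Hsp70 gene SSA3 at 1.90 (limma adjusted p = 0.0608), RPN4 at 1.36 and CTT1, with 0 day replicate 1 at the floor, at 3.24. The other fixed genes ranged from -0.18 for ERG11 to 1.61 for SSA4, with 0 called by limma, 3 of those 10 at an unadjusted p under 0.05 and OLE1, GPD1, TPS1 and TSL1 below 0 without 0 day replicate 2. On unnormalised values 10 of the 13 fixed genes passed the threshold. For amino acid biosynthesis the median was -0.41 (-0.38 within set 1 and -0.39 within set 2). LYS9 fell over all genes tested, and 10 fell and 2 rose when adjusted over the list alone. Camera gave adjusted p = 4.15e-06 with the preset correlation and adjusted p = 0.349 with an estimated correlation. The aminoacyl-tRNA synthetases had a median of -0.50 (-0.26 within set 1 and -0.80 within set 2, and -0.82 without 7 day replicate 2), with CDC60 at -1.13 and HTS1 at -0.90 and 0 genes called by limma over all genes tested or when adjusted over the list alone. With the preset correlation, camera gave adjusted p = 2.04e-05 for this list, against adjusted p = 0.363 with an estimated correlation. The iron and copper uptake list had a median of -0.55 (-0.68 within set 1 and -0.43 within set 2), and -0.26 and -0.83 without 0 day replicates 1 and 2. In it, SMF3 fell, and 6 fell when adjusted over the list alone. For this list, the camera test gave adjusted p = 1.59e-04 with the preset correlation and adjusted p = 0.363 with an estimated correlation.

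Camera called 19 of 37 lists at 7 days, 11 higher and 8 lower, 0 of them with an estimated correlation, and fry called 5. Without 0 day replicate 2 it called 9 lists, 2 of them higher, and without 7 day replicate 1 it called 12, of which 4 were higher. On unnormalised values the median of all genes was 0.98, against 0.17 here, and the list medians for amino acid biosynthesis (0.46), aminoacyl-tRNA synthetases (0.48) and iron and copper uptake (0.32) lay above 0 and below that median. That of ribosomal proteins was -0.03, and the call of the synthetases ended (camera adjusted p = 0.0537). There, 1413 of 1422 called genes were higher, and with equal array medians 31 of 35, against 6 of 11 here, while 9 of 13 called lists were higher on unnormalised values. Unadjusted p was under 0.05 for 985 genes. The count of 11 genes was 152 without 0 day replicate 1 and 20 without 0 day replicate 2. It was 0 without 3 day replicate 1 or either 14 day array, and 2 and 5 without 7 day replicates 2 and 1. With array set as a block it was 83.

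After 3 days, yeast could not be told apart from 0 days at the level of single genes. Limma called 0 of 5188 genes, with a smallest Benjamini-Hochberg adjusted p of 0.215. Unadjusted p was under 0.05 for 364 genes, where 259 were expected by chance, and 60 genes differed at least 2-fold in all 4 pairings of arrays. In the simulated 14 against 0 day comparison, with the same number of arrays and 200 genes changed, 83.6% of 8-fold changes were recovered, but 6.60% of 2-fold changes. The share recovered depends on how many genes change, so it need not hold at 3 days and may be lower there. The count was 16 without 0 day replicate 2 and 3 without 3 day replicate 1.

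The most extreme values at 3 days were log2 fold changes of 3.85 for YHR022C, 3.70 for RSF1, a regulator of respiratory growth, and 3.08 ± 0.47 SE for FUB1 (limma adjusted p = 0.215). At the other end were CDC55, a regulatory subunit of protein phosphatase 2A (-3.91), YBR071W (-3.88) and the spindle pole protein SPC72 (-3.70). Apart from FUB1 these had group mean signals of 2.77 to 4.07 in the dimmer group, near the floor of 2.52. The 54 genes of the cell wall and cell integrity list had a median of -0.34 (-0.54 within set 1 and -0.21 within set 2), and 0 were called by limma over all genes tested or when adjusted over the list alone. SCW10 and CRH1, which act on wall glucans, had values of -1.37 and -1.66, and a second probe set of SCW10 gave -2.49. It was the 1 list that camera called, with adjusted p = 8.01e-06 with the preset correlation and adjusted p = 0.826 with an estimated correlation, and fry called 0. On unnormalised values camera called 9 lists, 5 of them higher, and with equal array medians 7, of which 3 were higher. It called 12 lists without 0 day replicate 2 and 7 without 0 day replicate 1.

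Heat shock and ribosomal protein genes had medians of 0.11 and 0.06 at 3 days. Among the fixed genes, CTT1, with 0 day replicate 1 at the floor, had a log2 fold change of 2.11 and SSA4 one of 0.89, with OLE1 at -1.35, TSL1 at -1.40, GPD1 at -1.27 and TPS1 at -1.11 (smallest limma adjusted p = 0.651, for OLE1). Without 0 day replicate 1 these last 4 were at -0.68, -0.01, -0.11 and -0.10. UBI4 and SOD2 were at -0.64 and -0.69. HSP104 (0.05), HSP12 (-0.11), HSP26 (0.01), ERG11 (-0.12) and RPN4 (-0.32) each changed sign in at least 1 alternative. Members of other lists with the smallest p were USV1 (-3.63, with 3 day replicate 2 at the floor) and GRE1 (-2.09) of the general stress list, SNF3 (-1.42) and IMA1 (-1.32) of the sugar uptake list, and TIF4632 (-1.98) and EFB1 (-0.62, with -0.31 for a second probe set) of the translation factors. The same held for FRS2 (-0.95) and THS1 (-0.58) of the tRNA synthetases and for IDH1 (-0.89) and IDP1 (-0.68) of the TCA cycle. Fold changes at 3 days correlated with those at 7 days at r = 0.345 and with those at 14 days at r = 0.291, below the 0.501 and 0.498 that simulated unchanged groups gave. The covariances exceeded the simulated ones by 0.0421 and 0.0266. The simulation gave every time the same spread, while the shared 0 day arrays differed most, so this excess decides nothing. With a different 0 day array for each comparison, r was -0.209 or 0.057 with 7 days and -0.221 or 0.047 with 14 days.

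**Figure D2:**
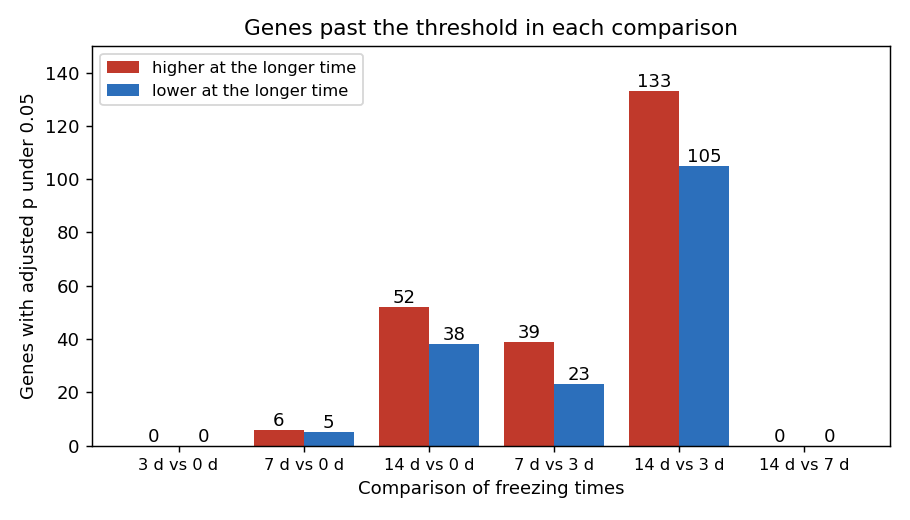
Number of genes past an adjusted p of 0.05 (y axis) in 6 comparisons of freezing times (x axis), higher in red and lower in blue at the longer time. The comparison of 14 with 3 days had 133 and 105 genes, and those of 3 with 0 days and 14 with 7 days had 0.

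For the mean of the 3 frozen groups, 5 genes differed from 0 days. ROQ1 (log2 fold change 2.84), FUB1 (3.32), DIC1 (2.44) and YHR022C (3.91) rose, and RNR1 fell (-2.69), with limma adjusted p of 0.0162 for FUB1 and 0.0384 for ROQ1, DIC1 and RNR1. Unadjusted p was under 0.05 for 910 genes. On unnormalised values 582 of 589 called genes were higher, and with equal array medians 5 of 5, against 4 of 5 here. The count was 64 and 49 without 0 day replicates 1 and 2 and 0 without 3 day replicate 2, 7 day replicate 1 or either 14 day array, and 1 without 3 day replicate 1.

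Samples frozen for 3 days differed from those frozen for 7 and 14 days, though a processing batch cannot be told apart from freezing time. The count of genes between 3 and 14 days was above that between 3 and 7 days, but on unnormalised values it was 295 against 620. At 14 days 133 genes were higher and 105 lower than at 3 days (limma, Benjamini-Hochberg adjusted p under 0.05). ROX1 rose 16.3-fold (log2 fold change 4.02 ± 0.45 SE, n = 2 per group, limma adjusted p = 0.00584), and OPT2 fell 10.7-fold (-3.42 ± 0.42 SE, limma adjusted p = 0.00697). IDH1 rose 10.9-fold and HAP4 5.82-fold. Since both times were set against the same 0 day arrays, this comparison is also the test of whether their changes from 0 days differed.

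The other large rises from 3 to 14 days were SRL3 (log2 fold change 3.94), ECM13 (3.90), ANS1 (3.62) and CDC55 (3.61). CDC55 had a 3 day mean signal of 3.09, near the floor, and SRL3 was at the floor of 2.52 in 3 day replicate 1, with values of 2.80 without that array and 5.10 without 3 day replicate 2. The other large falls were ADY4 (-4.09, with 14 day replicate 1 near the floor), RNR3 (-3.81), the mating pheromone gene MF(ALPHA)1 (-3.65) and YDL085C-A (-3.50). Limma adjusted p ranged from 0.00584 for ANS1 to 0.0406 for CDC55. The call of SRL3 ended in 8 of 18 alternatives and that of CDC55 in 8 of 17.

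Cytosolic ribosomal protein genes fell between 3 and 14 days in 17 of 81 cases over all genes tested and in 36 when adjusted over the list alone. RPL7B fell 6.88-fold (log2 fold change -2.78 ± 0.50 SE, limma adjusted p = 0.0215) and RPS1B 5.20-fold (-2.38 ± 0.31 SE, limma adjusted p = 0.00917). Both were read by probe sets that can bind near-identical copies, and a second probe set of RPL7B gave -1.65. The list median was -0.67, with -0.62 within set 1 and -0.63 within set 2. The list was called by camera (adjusted p = 8.41e-17 with the preset correlation) but not when repeated, with adjusted p = 0.339 with an estimated correlation.

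Among heat shock genes, 9 of 32 rose over all genes tested and 19 when adjusted over the list alone, with a median of 0.92 (0.88 within set 1 and 0.96 within set 2). They included BTN2, which sorts misfolded proteins (log2 fold change 2.13 ± 0.39 SE, limma adjusted p = 0.0229), SSE2 (2.09), the mitochondrial co-chaperones MDJ1 (1.77) and HSP10 (1.33) and the sorting factor CUR1 (1.98). Camera gave adjusted p = 2.27e-09 with the preset correlation and adjusted p = 0.339 with an estimated correlation. General stress genes had a median of 1.41 (1.40 within set 1 and 1.51 within set 2), and 5 of 51 rose over all genes tested and 23 when adjusted over the list alone. These 5 were the reductase GRE2 (2.49 ± 0.58 SE), the phosphatase SDP1 (2.42 ± 0.60 SE), TFS1 (1.80), DDR48 (1.41) and HSP12 (1.39). The calls of GRE2 and SDP1 each ended in 8 of 19 alternatives. With the preset correlation, camera gave adjusted p = 7.60e-13 for this list, against adjusted p = 0.399 with an estimated correlation.

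Amino acid biosynthesis genes had a median of -0.64 (-0.75 within set 1 and -0.59 within set 2), with 8 of 54 lower and 1 higher over all genes tested, and 14 lower and 2 higher when adjusted over the list alone. LYS9 (-2.86), LYS12 (-2.70) and the asparagine synthetase ASN1 (-2.19) were among those that fell, and ARO9, an aromatic aminotransferase, rose (2.14). For this list, the camera test gave adjusted p = 2.52e-07 with the preset correlation and adjusted p = 0.339 with an estimated correlation. In the TCA cycle, IDH1 (3.45), IDH2 (2.77), ACO1 (2.55) and FUM1 (2.33) rose, 4 of 19 genes over all genes tested and 11 when adjusted over the list alone. The list median was 1.41 (1.24 within set 1 and 1.57 within set 2), and camera gave adjusted p = 8.56e-07 with the preset correlation and adjusted p = 0.382 with an estimated correlation. Trehalose and glycogen genes had a median of 1.21 (1.13 within set 1 and 1.34 within set 2), and the glycogen synthases GSY2 (2.90) and GSY1 (1.91) rose. Of 22 genes, 4 rose when adjusted over the list alone, and camera gave adjusted p = 0.00112 with the preset correlation and adjusted p = 0.422 with an estimated correlation.

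**Figure D3:**
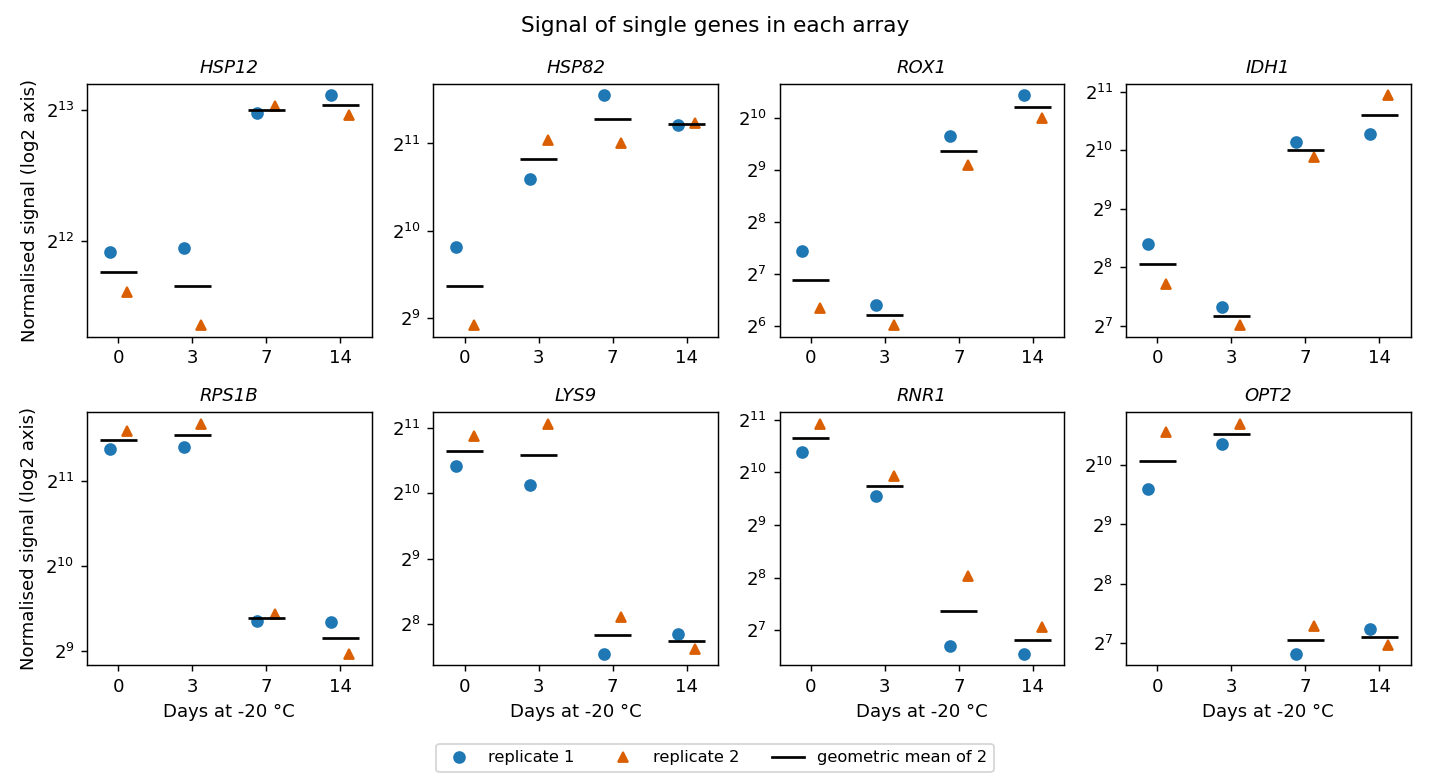
Normalised signal on a log2 axis of HSP12, HSP82, ROX1, IDH1, RPS1B, LYS9, RNR1 and OPT2 in each of the 8 arrays against days at -20 °C. Circles are replicate 1, triangles replicate 2 and lines the geometric mean of both. For RPS1B the means were 2856 at 0 days, 2973 at 3 days, 674 at 7 days and 572 at 14 days.

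Camera called 20 of 37 lists between 3 and 14 days, 12 higher and 8 lower, 0 of them with an estimated correlation, and fry called 6. Of the 90 genes called at 14 against 0 days, 38 that rose and 30 that fell were also called against 3 days, where 1.33 and 0.769 would arise from independent lists, and the shared 14 day arrays contribute to this overlap. Unadjusted p was under 0.05 for 1276 genes. The count of 238 genes was 3 without 3 day replicate 2, 2 and 6 without 14 day replicates 1 and 2, 118 without 3 day replicate 1, 121 and 134 without 7 day replicates 2 and 1, and 440 without either 0 day array. With array set as a block it was 403, and on unnormalised values 223 of 295 called genes were higher, against 133 of 238 here.

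Between 3 and 7 days, 39 genes rose and 23 fell. ANS1 rose 12-fold (log2 fold change 3.59 ± 0.42 SE, limma adjusted p = 0.0121), and the 18S ribosomal RNA gene RDN18-1 rose 10.5-fold (3.40 ± 0.57 SE, limma adjusted p = 0.0350), whose probe set reads RNA that poly(A) enrichment should remove. OPT2 (-3.47 ± 0.42 SE, limma adjusted p = 0.0121) and MF(ALPHA)1 (-3.24 ± 0.61 SE, limma adjusted p = 0.0452) fell. Of these genes, 37 that rose and 22 that fell were also called between 3 and 14 days, where 1.0 and 0.465 would arise from independent lists and the 3 day arrays are shared. On unnormalised values 598 of 620 called genes were higher, and with equal array medians 50 of 66, against 39 of 62 here. The count was 0 without 7 day replicate 2, 8 without 7 day replicate 1, 2 without 3 day replicate 2 or either 14 day array, and 229 and 225 without 0 day replicates 1 and 2.

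Between 7 and 14 days limma called 0 genes, with an unadjusted p under 0.05 for 48 genes where 259 were expected by chance. The fit shares a residual variance across all times. Replicates correlated at r = 0.877 at 0 days, against 0.938 at 7 days and 0.927 at 14 days, so equal spread is doubtful. The shared variance may be too large for this pair and too small against 0 days. Fitting only the compared groups also called 0 genes, but the 0 calls do not show that 7 and 14 days were alike. By the rule of at least 2-fold in all 4 pairings of arrays, 19 genes differed, and 6 were called by limma without 7 day replicate 1. The F test among the 3 frozen times called 117 genes, with an unadjusted p under 0.05 for 973. That count was 239 and 232 without 0 day replicates 1 and 2, 24 and 1 without 3 day replicates 1 and 2, 52 and 48 without 7 day replicates 1 and 2, and 6 without either 14 day array.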

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

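The tests of degradation, batch and the 0 day arrays were chosen after the results were seen, and the test of scaling was written before.

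The change from 0 days differed between 14 and 3 days for 238 genes and between 7 and 3 days for 62 genes, by limma's test of the difference itself. These counts drew attention because time points under the same contrast differed. Camera called 20 gene lists between 3 and 14 days with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.339), and fry called 6. All 20 lists kept the sign of their median relative to all genes on unnormalised values and with equal medians, but a scale factor per array cancels in that measure, so the planned test could not decide on array scales. Degradation could not be decided from the 3' to 5' ratios. At 14 days 0 of the 4 ratios of ACT1 and SPT15 lay outside the range of the 0 and 3 day arrays. That range was wide, 1.41 to 2.86 for ACT1 and 2.07 to 4.32 for SPT15. Within set 1 the 14 day ratios (2.01 and 2.97) lay above those of 0 and 3 days, and within set 2 (2.23 and 3.16) below them. A processing batch that parts early from late samples cannot be told apart from freezing time. The hybridisation controls differed by -0.228 on the log2 scale between 14 and 3 days, with 14 day arrays at 651 and 447 and 3 day arrays at 710 and 563, which decides nothing. The spiked poly(A) signals at 0, 3, 7 and 14 days were 46.4, 62.1, 87.2 and 137 in set 1. In set 2 they were 127, 239, 846 and 448. They were higher at 7 and 14 days within each set, which does not tell a batch from freezing time. Longer freezing, which the design names, stays an open and untested explanation.

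The 0 day arrays differed from each other more than other replicates did. With 2 arrays it was left open which of them represents the group, and every value against 0 days depends on it. The ACT1 3' to 5' ratio of replicate 1 was 1.54, below the median of the other arrays. Every set 1 array (1.41 to 2.01) lay below every set 2 array (2.16 to 2.86), so this could not decide on degradation of replicate 1. The ratio of replicate 2, 2.86 and the highest, lay close to the 2.78 of 3 day replicate 1 and decides nothing. Whether replicate 1 was a 7 or 14 day sample under its label could not be decided from correlations. Its highest was r = 0.884, with 7 day replicate 2, against at least 0.927 among the 7 and 14 day arrays. Its r was no higher with the early arrays, at 0.877 with 0 day replicate 2 and 0.881 and 0.866 with 3 day replicates 1 and 2. A merely noisy array is argued against by 4 gene lists whose median differed by over 1 on the log2 scale between the 0 day arrays, 1.44 for gluconeogenesis, 1.43 for trehalose and glycogen, 1.38 for general stress genes and 1.04 for sugar uptake. Replicate 1 also lay above replicate 2 at 3, 7 and 14 days, though by less, for gluconeogenesis (0.26, 0.73 and 0.33). The same held for trehalose and glycogen (0.57, 0.89 and 0.60) and general stress genes (0.32, 0.53 and 0.41). Sugar uptake differed by only -0.11, 0.05 and 0.06. Part of the difference may thus go with the replicate number at every time, which was not tested. A difference in the state of the cells remains possible and was not tested.

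Control probe sets for ribosomal RNA, which are left out of the tests of genes, were higher at 14 days than at 0 days by 1.26 on the log2 scale (SD 0.33 and 0.27, n = 2 per group) and by 1.35 at 7 days. The probe sets differed, with deposited signals of 1482 and 375 at 0 days and 692 and 2136 at 14 days for a 25S probe set against 886 and 593 and then 4030 and 2955 for the 18S one. They drew attention as a signal outside the main measurement that exceeded the 0 day level.

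Among 1307 probe sets that name no gene or several genes, 47 differed between 14 and 3 days by limma with Benjamini-Hochberg adjustment, 23 higher and 24 lower. They drew attention because the comparisons by gene leave them out. Of the genes, 238 of 5188 were called between these times, so the share among these probe sets was not higher.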

How the results depend on the processing

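The array set block and the tests it enters were added after the data were seen, and all other alternatives were planned. Counts of called genes depended on the setting, while 0 of the genes called in the text's comparisons changed sign in the alternatives where signs were compared. Without the intensity trend, with a block, with only the compared groups or with stricter thresholds the fold changes cannot move. Called genes were also selected for large changes in these same arrays, so their kept signs say little. Signs were not compared for the F test, with all probe sets counted or by the rule of at least 2-fold in all pairings.

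Counts are given for 14 against 0 days (90 genes), 7 against 0 days (11), the mean of the frozen groups (5), the F test (117), 14 against 3 days (238) and 7 against 3 days (62), in that order and only where they moved by over 1.5 times; the cause was not tested unless fewer genes, arrays or a stricter rule give it. On unnormalised values they were 403, 1422, 589 and 353, and 620 for 7 against 3 days. With equal array medians they were 48, 35 and, for the F test, 70. With a pseudocount 7 against 0 days gave 53 and 7 against 3 days 127. Without a filter the mean gave 2 and the later ones 34, 152 and 21, and with a filter at the median those against 0 days were 137 and 58, the F test 185 and 7 against 3 days 150. Without the intensity trend they were 11, 0, 3, 0, 18 and 0. With array weights all but 7 against 0 days were 17, 1, 226, 378 and 252. Fitting only the compared groups gave 0 for 14 against 0 days, 242 for the F test and 105 for 7 against 3 days. With array set as a block they were 222, 83, 17, 203, 403 and 169. At an adjusted p under 0.01 they were 0, 0, 0, 4, 6 and 0. Counting all probe sets gave 21 for 7 against 0 days and 2 for the mean. At least 2-fold in all pairings of arrays gave 328, 256, 483 and 371 for the pairs, 60 for 3 against 0 days and 19 for 14 against 7 days.

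With the replicate number as a block the counts were 158, 37, 11, 218, 430 and 205, and 6 lists were called at 3 days. Deviations of samples with the same number correlated at -0.0884, 0.0858 and 0.0484 between 0 days and 3, 7 and 14 days. Deviations of samples in the same array set correlated at 0.0884, -0.0858 and -0.0484 there, so that block was no better founded against 0 days. Among the frozen times, where the array sets hold the same pairs, they correlated at 0.178 (3 and 7 days), 0.195 (3 and 14 days) and 0.292 (7 and 14 days). The rule fixed in advance asked for over 0.1 in every pair of times and was not met for the pairs with 0 days, so the shared fit has no block. For the frozen times alone a pairing stays open.

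Leaving out 1 array gave 0 to 245, 0 to 152, 0 to 64, 1 to 239, 2 to 440 and 0 to 229 genes, 0 to 16 at 3 days, and 0 to 6 for 14 against 7 days. Lists called by camera ran from 12 to 25 at 14 days (22 with all arrays), 9 to 24 at 7 days (19), 1 to 12 at 3 days (1) and 19 to 21 for 14 against 3 days (20). Lists at 3 days were 9 on unnormalised values, 7 with equal medians, 4 with the median filter and 2 with array weights, a pseudocount or only the compared groups. With an estimated correlation, which also brings the residual degrees of freedom of the fit into the test, lists fell to 0 in every comparison. Fry gave 9, 5, 6 and 0 lists for 14, 7, 14 against 3, and 3 days.

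These directions reversed. On unnormalised values EFB1 (0.00322), ERG11 (0.47), HSP12 (0.39) and RPN4 (0.0335) at 3 days, ERG11 (0.35) and HTS1 (0.11) at 7 days and ERG11 (0.0102) at 14 days were positive. With equal medians ERG11 (0.30) and HSP12 (0.23) at 3 days were positive, and with a pseudocount HSP26 was -0.0153. Without single arrays the ranges were -0.78 to 0.34 for ERG11, -0.27 to 2.04 for GPD1, -0.27 to 1.08 for OLE1, -0.77 to 2.05 for TSL1 and 0.0804 to 1.52 for the trehalose list at 14 days, where camera's direction turned and the median stayed positive. At 7 days they were -0.46 to 1.84 for GPD1, -0.29 to 1.06 for OLE1, -0.29 to 1.77 for TPS1, -1.12 to 1.69 for TSL1, and, likewise by camera's direction alone, 0.0250 to 1.69 for gluconeogenesis, 0.0121 to 1.16 for sugar uptake and 0.16 to 1.13 for vacuolar proteases. At 3 days they were -0.25 to 0.0236 for ERG11, -0.17 to 0.27 for HSP104, -0.39 to 0.18 for HSP12 and -0.84 to 0.89 for HSP26. With 1 control array per comparison the correlation of 3 day fold changes became -0.21 or 0.06 with 7 days and -0.22 or 0.05 with 14 days, and that of 7 with 14 days 0.36 or 0.38, since the shared arrays no longer enter both. Signal over background limits YHR022C, whose mean of 3.39 at 0 days lay near the floor of 2.52.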

Other observations

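The comparison of the ribosome lists was chosen after the results were seen. Genes for membrane lipids, glycolysis and cell identity were not called as groups at 14 days. The lists of ergosterol synthesis (median log2 fold change -0.15 at 14 against 0 days), fatty acid and phospholipid synthesis (0.05), sphingolipids and stress-induced membrane proteins (0.23) and glycolysis and fermentation (-0.02) were not called by camera. The same held for proline and arginine metabolism (-0.06), methionine and sulfur metabolism (0.08), sporulation (0.09), haploid and mating genes (-0.02) and housekeeping genes (0.08). The glycerol and osmotic stress list had a median of 0.56 and was not called by camera (adjusted p = 0.295), but was by fry (adjusted p = 0.0432).

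Genes for the proteasome and for RNA polymerase subunits were called as lists at 14 days as well. The 40 proteasome genes had a median of 0.50 (0.48 within set 1 and 0.47 within set 2), with camera adjusted p = 0.0217 and adjusted p = 0.350 with an estimated correlation. The call ended without 0 day replicate 2 (0.36) and without 14 day replicate 2 (0.35). Limma called 0 of them over all genes tested or when adjusted over the list alone. The 25 genes of RNA polymerases I and III, which make ribosomal and transfer RNA, had a median of -0.42 (-0.43 within set 1 and -0.59 within set 2), with camera adjusted p = 0.00165 and adjusted p = 0.324 with an estimated correlation. That median was 0.11 on unnormalised values, where the median of all genes was 0.59.

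Ribosomal protein genes had a lower median (-0.60, with -0.57 within set 1 and -0.62 within set 2) than the 105 ribosome biogenesis genes, whose median was -0.17 at 14 days (0.21 within set 1 and -0.54 within set 2). That median was 0.35 on unnormalised values, 0.05 without 0 day replicate 2 and -0.45 without 0 day replicate 1, and -0.07 and -0.30 without 14 day replicates 1 and 2. Camera on the 186 genes of both lists alone gave p = 0.029 with an estimated correlation of 0.122 (3.36e-11 with the preset correlation), with ribosomal protein genes ranked lower. Within set 2 the medians lay close together, though the sets are only 1 way to pair the arrays with those of 0 days. Relative to the 0 day mean, ribosomal protein genes lay at -0.59 and -0.63 in 14 day replicates 1 and 2, and biogenesis genes at -0.30 and -0.07. The test restates the observation that prompted it, so whether the lists respond to different extents stays open.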
